A study of Mus musculus with 31 samples.

How the data were processed

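Biotin-labelled total RNA was hybridised to 31 Affymetrix mouse expression arrays, 1 array per sample, per the labels. The labels place the arrays in 10 groups of mouse CD4 T cells: induced regulatory T cells (induced Treg, 5 arrays), cells of the same cultures that did not switch on the Foxp3 reporter (failed induced Treg, 3), induced cells carrying a mutant Foxp3 reporter allele (induced Foxp3-delta, 3), activated T cells (4), activated natural Treg (3), natural Treg (4), natural Foxp3-delta cells (2), conventional T cells (3), and induced Treg and induced Foxp3-delta cells kept for 1 further week in interleukin 2 at 100 units per ml (2 and 2). Induction lasted 3 days, per the labels' protocols. The labels number the samples of each group and do not say that they came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every comparison.

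The deposited values are probe set intensities on a linear scale, per the file itself. How the authors summarised the probes, corrected the background and scaled the arrays is not given in the sources used here, so the scale and centring of the deposited intensities stay unknown. The arrays had not been brought to a common level: the deposited median intensity was 42.31, 42.76, 42.23, 55.42 and 37.08 on the arrays labelled induced Treg 1 to 5, 45.83, 44.01 and 37.38 on failed induced Treg 1 to 3, 53.08, 44.4 and 34.68 on induced Foxp3-delta 1 to 3, and 40.76, 26.48, 22.21 and 31.81 on activated T 1 to 4. It was 24.16, 27.19 and 29.34 on activated natural Treg 1 to 3, 41.8, 46.29, 47.73 and 39.04 on natural Treg 1 to 4, 52.7 and 31.74 on natural Foxp3-delta 1 and 2, and 47.42, 44.28 and 43.18 on conventional T 1 to 3. The arrays labelled as cultured in interleukin 2 had medians of 37.04 and 39.54 (induced Treg) and 39.74 and 42.65 (induced Foxp3-delta). Correlations between arrays ran from 0.983 to 0.996 within label groups and from 0.98 to 0.996 between them, so no array repeated another, and each was counted as 1 sample.

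The table held 45101 probe sets. Through the platform annotation, 34958 carried 1 gene symbol, 932 carried several and 9211 carried none that was listed. 64 were Affymetrix controls. Probe sets with several symbols were not named. Each of 18194 genes was represented by the probe set with the highest mean over all arrays, and 12169 genes that lay above the table's median (an intensity of 39.82 after scaling) on at least 2 arrays were tested. Probe sets of 1 gene can disagree, and the mean of all probe sets of a gene was tried as an alternative.

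Arrays were quantile normalised between arrays and analysed as log2(intensity + 16), so every log2 difference is on that scale and understates the change of genes of low intensity. Values as deposited had been planned as the setting for the comparisons. Quantile normalisation was taken in their place after the array medians had been seen and before any test was run, because the arrays were not on a common level, and the planned setting is reported as an alternative. A linear model with 1 mean per group was fitted over all 31 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that all groups shared 1 estimate of the spread. 12 contrasts of label groups and a pair of interaction contrasts were tested, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05.

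Gene lists (23, written from textbook knowledge before the data were examined, for T cell programmes, metabolism, stress, other blood cell types and sex-linked genes) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. 20 of them had tested members, and 3 (effector cytokines, CD8 and natural killer cell markers, and red cell markers) had none. A transfer test was planned for genes that differed at least 2-fold between arrays labelled natural Treg and conventional T. It could not be run, since 0 genes were higher and 1 was lower at that size.

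Genes were named by a rule fixed before the data were examined: Foxp3, then the called genes with the largest changes whose groups did not overlap on any array (up to 6 per direction in a main comparison and 3 in a secondary one, symbols of unnamed gene models left out), then, for a list that is described, up to 4 called members or the member with the smallest p. The contrasts, the lists, the naming rule and the alternatives so described below were fixed before the data were examined. Chosen after values had been seen were the quantile normalisation, 9 marker lists of tissues and housekeeping genes used to check what RNA the arrays measured, the 3 array sets described next, the alternatives that use them, and which of the fixed lists have their members named.

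The labels give no batch. Ward clustering of the arrays on the log2 ratio of the cre to the bioB hybridisation controls, the median and the 99th percentile of deposited intensity gave 3 technical array sets of 15, 6 and 10 arrays. The alternatives fixed beforehand were values as deposited, centring on array medians, pseudocounts of 1 and 64, no filter, a filter at the 70th percentile, the mean of probe sets, a fit of the compared groups alone, the replicate number as a block, an intensity trend with a robust prior, array quality weights, and leaving out each array in turn. Those added after values had been seen repeat each comparison with the array set as a block, with the control ratio as a covariate, within each set where both groups had an array there, and without set 3.

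The procedure was tested on simulated data drawn from the genes' own means and residual spreads, with known changes added. With a log2 change of 1 in 100 of 12169 genes, 96 were recovered for natural Treg against conventional T, 100 for induced Treg against induced Foxp3-delta and 87 for the same pair after interleukin 2. At a log2 change of 0.5 the numbers were 71, 72 and 46, with 9, 11 and 2 false calls over both sizes. The simulated noise was independent between genes and arrays and held no array sets. The few false calls therefore say nothing on false calls that array sets may cause in the real data.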

Results

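The series asks how natural and induced regulatory T cells (Treg) resemble and differ from each other and from conventional T cells, and what the transcription factor Foxp3 adds, by comparing cells with an intact Foxp3 reporter allele with cells that carry a mutant one. Expression was measured on 31 arrays in 10 label groups of 2 to 5. Because Foxp3 defines the groups, its level is given first. The Foxp3 probe set read between 7.6 and 17.0 intensity units on the 31 arrays. It averaged 13.8 ± 1.84 (SD, n = 4) on the arrays labelled natural Treg, 13.1 ± 1.19 (n = 5) on those labelled induced Treg and 13.8 ± 0.986 (n = 3) on those labelled conventional T. Bacterial control probe sets for which nothing is spiked in had a median of 8.54 and a 95th percentile of 14.3 over 27 probe sets. The log2 difference in Foxp3 between natural Treg and conventional T labels was 0.02 (SE 0.07, 95% interval -0.12 to 0.16), and between induced Treg and activated T labels it was -0.02 (SE 0.06, interval -0.15 to 0.10).

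Genes of T cell identity were low on every array as well. The median of the 17 measured T cell genes lay at percentile 38.5 of an array's probe sets on average, between 34.9 and 46.6 over the 31 arrays. Cd3e and Cd3d, chains of the T cell receptor complex, averaged 36.8 ± 12.2 and 14.9 ± 3.22 (SD, n = 31), Cd4 averaged 19.8 ± 3.85, Cd2 11.2 ± 1.72, and Cd28, the costimulatory receptor, 12.8 ± 1.62. 11 of the 17 lay on average in the lower part of the array, under percentile 50. The exception above percentile 90 was Thy1 (5432 ± 1667), which neurons also express. The 26 measured genes of the Treg list had a median percentile of 49.1 and the 23 genes of the activation list one of 50.3.

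Genes of nervous tissue were instead among the brightest probe sets on every array. Mbp, the major myelin protein, averaged 19990 ± 3247 (SD, n = 31), Mobp 14900 ± 2939, Cnp 14770 ± 2911, the synaptic proteins Cplx1 and Snap25 14660 ± 2647 and 10350 ± 2736, the neurofilament gene Nefl 12500 ± 2483, and the astrocyte genes Aldoc and Gfap 15380 ± 3879 and 5150 ± 1568. The median percentiles were 99.4 for 9 myelin genes, 99.5 for 12 neuron genes and 99.2 for 9 astrocyte genes, and 83.2 for 8 microglia and macrophage genes, against 99.2 for 10 housekeeping genes, 27.3 for liver, 34.7 for muscle and 15.7 for kidney and gut genes. Among lists of other blood cells, B cell genes lay at 28.1, CD8 and natural killer cell genes at 23.5 and red cell genes at 30.4, and cell cycle genes lay at 44.5. The 100 brightest probe sets covered 79 genes, of which 12 belonged to the myelin, neuron or astrocyte lists and 0 to the T cell, Treg or activation lists. These tissue lists were drawn up after the top probe sets had been seen.

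Sex-linked genes were alike on all arrays. Xist, the transcript of the inactive X chromosome, read between 1719 and 4523, and the Y-linked genes Eif2s3y, Kdm5d and Uty read at most 11.2, 11.7 and 12.3. The groups labelled induced Foxp3-delta came from mutant males per the labels, and there Xist averaged 3450 ± 933 (SD, n = 3) and, after interleukin 2, 2450 ± 69.2 (n = 2). The measured values therefore go against the labels, and each group below is given as the arrays labelled with its name.

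**Figure D1:**
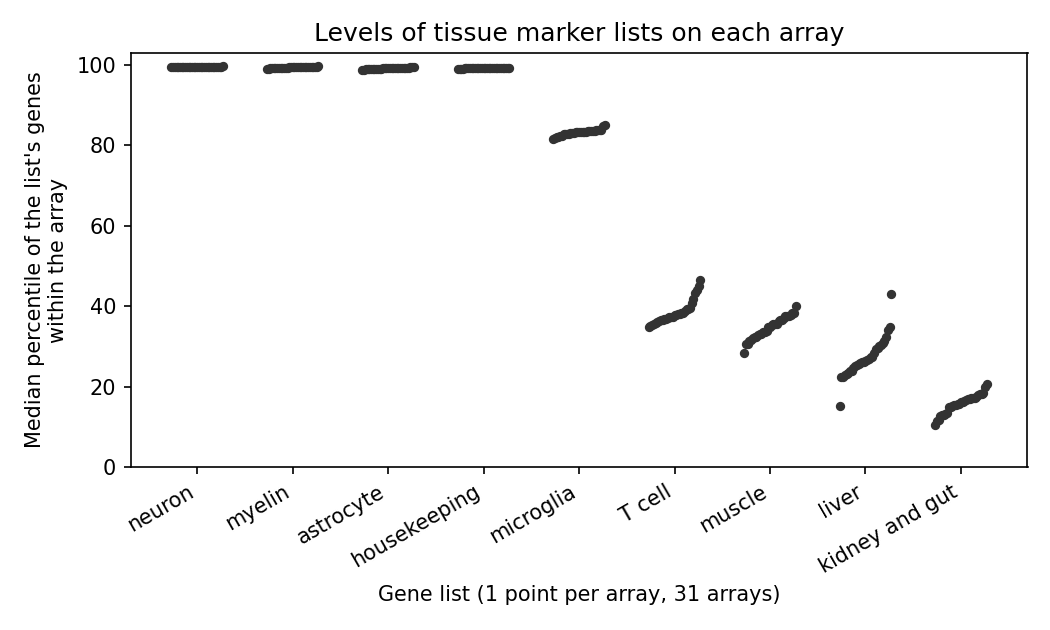
Median percentile of the genes of each marker list within an array (vertical axis, percent of probe sets; 1 point per array, 31 arrays per list, sorted within a list). The neuron, myelin, astrocyte and housekeeping lists lie between 98.8 and 99.7 on every array, and the T cell list lies between 34.9 and 46.6.

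The arrays also differed technically. The deposited median intensity ran from 22.2 to 55.4, and the log2 ratio of the cre to the bioB hybridisation controls, which are added in fixed amounts, from 5.02 to 6.44. Clustering on these and on the 99th percentile gave 3 array sets. Set 1 (15 arrays) held every array labelled natural Treg (4), conventional T (3), induced Treg with interleukin 2 (2) and induced Foxp3-delta with interleukin 2 (2), with 2 of failed induced Treg and 2 of induced Treg. Set 2 (6 arrays) held 2 of induced Treg, 2 of induced Foxp3-delta, 1 of natural Foxp3-delta and 1 of activated T. Set 3 (10 arrays) held the 3 of activated natural Treg, 3 of activated T, and 1 each of induced Treg, failed induced Treg, induced Foxp3-delta and natural Foxp3-delta. Over the 12169 tested genes the closest array was of the same set for 31 of 31 arrays and of the same label group for 8 of 31. These counts are not on one scale, since groups are smaller than sets and match less often by chance. Label group took up 44.1% of the variance (30% expected of random groups) and array set 34.6% (6.67% expected of random sets). Set and group together took up 60.1%, so a part of these shares is common to both. The sets were defined from the data, so each count of genes is given with the set as a block as well.

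**Figure D2:**
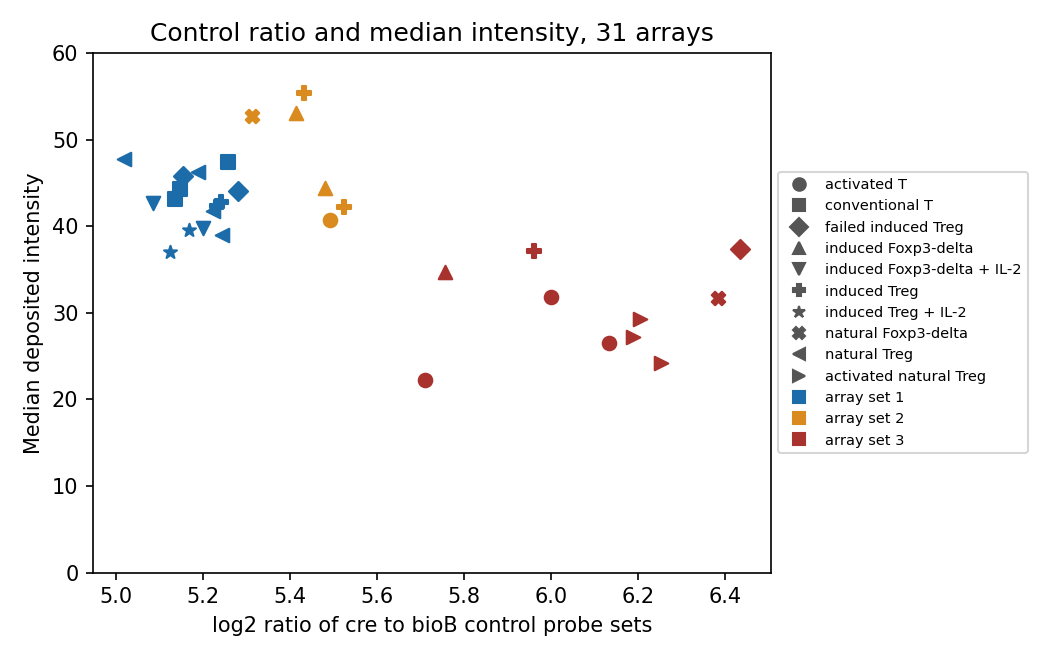
Log2 ratio of the cre to the bioB control probe sets (horizontal axis) against the median deposited intensity (vertical axis) of the 31 arrays, with label group as the symbol and array set as the colour. Set 3 has ratios of 5.71 to 6.44, above the 5.02 to 5.53 of sets 1 and 2, and holds all 3 arrays labelled activated natural Treg and 0 of the 7 labelled natural Treg or conventional T.

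The arrays labelled natural Treg and conventional T, which ask what marks a Treg taken from the animal, differed in a single called gene. Ggt5, a gamma-glutamyltransferase that acts on leukotrienes, fell by 1.13 on the log2 scale (SE 0.17, limma adjusted p = 0.0112), from 7.58 ± 0.13 (SD, n = 3) to 6.45 ± 0.16 (n = 4), with no overlap between the groups. No member of the Treg list passed. Tnfrsf9, a costimulatory receptor of that list, came closest, with a log2 difference of 0.41 (SE 0.08, adjusted p = 0.172). Of 12169 genes, 0 were called higher and 1 lower, and 321, 2.64% against 5% by chance, had an unadjusted p under 0.05. Of all genes 6.72% separated the groups completely against 5.71% by chance. Over 188 tested members of the gene lists, 0 passed over all genes and 4 (3 higher and 1 lower) adjusted over the list alone. Here and below, counts of list members are summed over the lists, so a gene in several lists counts once in each. The smallest adjusted p of any list by camera was 0.129, and here as in every later comparison no list passed with a preset or with an estimated correlation. With the array set as a block 3 genes were called, Tnfrsf9 among them at an unchanged fold (0.41, limma adjusted p = 0.000639). All arrays of both groups were in set 1, so the block changed only the estimate of the spread here. The spread shared by all groups in the main fit also takes in differences between sets within other groups. The single call therefore does not show that these labels hardly differ. Ggt5 in natural Treg versus conventional T was not called as deposited (adjusted p = 0.401), with the mean of its probe sets (0.378), without array set 3 (0.0705), which holds no array of these groups, or without natural Treg array 1 (0.0827), natural Treg array 2 (0.0623), conventional T array 1 (0.0722) or conventional T array 3 (0.139). Its fold was -0.36 with the mean of probe sets and between -1.14 and -1.07 in the others of these settings. The count was 0 without any 1 of these 4 arrays, 3 without natural Treg array 3 and 2 without natural Treg array 4.

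Against the arrays labelled conventional T, those labelled natural Foxp3-delta were higher in Ttyh3, a chloride channel gene (log2 difference 1.39, SE 0.29), Notch3, a Notch receptor of vascular mural cells (1.05, SE 0.22), and Ssc4d, a scavenger receptor family member (1.00, SE 0.21). They were lower in the myosin gene Myo1e, which fell by 0.76 (SE 0.14), the spliceosomal gene Snrpb2, by 0.74 (SE 0.15), and the laminin chain gene Lamc1, by 0.69 (SE 0.15). Bcl2l1, which protects cells from apoptosis and was the only called member of the interleukin 2 and STAT5 list, was higher by 0.62 (SE 0.13, adjusted p = 0.0419). In all, 10 genes were called higher and 13 lower by limma (n = 2 and 3, adjusted p from 0.0419), and 1919 had an unadjusted p under 0.05. 1 list member passed over all genes and 16 adjusted over the list alone (8 higher and 8 lower), and no list passed by camera (smallest adjusted p = 0.305). For natural Foxp3-delta cells versus conventional T no gene was called with the array set as a block, as deposited, or with the mean of probe sets, and array medians gave 556 higher and 30 lower with a median shift of 0.14 over all genes. These groups share no array set, so the block rests on the other groups and cannot tell label from set here. With it the folds of the 7 named genes were at 79.7% of their size at the median. Leaving out natural Foxp3-delta array 2 or any 1 of the 3 conventional T arrays left 0 calls, and leaving out natural Foxp3-delta array 1 gave 135. Array 2 had the highest actin 3' to 5' signal ratio of all 31 arrays, 2.19 against 1.72 on array 1 and 1.79 to 1.80 on the conventional T arrays. Its Gapdh 3' to 5' ratio of 1.014 lay within the 0.999 to 1.027 of the conventional T arrays, and array 1 had 0.928.

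The direct comparison of arrays labelled natural Treg with natural Foxp3-delta, which asks what an intact Foxp3 allele adds, named 6 genes. Their groups did not overlap, which the naming rule requires. Of all genes tested, 30.5% separated these groups, against 13.3% by chance. Sptbn4, a spectrin of the axon initial segment, was higher by 1.07 (SE 0.18, adjusted p = 0.0147), Pls1, an actin-bundling plastin, by 0.90 (SE 0.13, adjusted p = 0.00226), Snrpb2 by 0.75 (SE 0.14) and the transcriptional repressor gene Etv3 by 0.56 (SE 0.10). Tle2, a Groucho corepressor, fell by 0.74 (SE 0.13) and Hexim2, an inhibitor of transcription elongation, by 0.69 (SE 0.12). Itgae, an integrin chain of the Treg list, had the smallest p of that list, with a difference of -0.40 (SE 0.12, adjusted p = 0.133). Foxp3 itself differed by 0.13 (SE 0.08, interval -0.03 to 0.29). 4 genes were called higher and 2 lower (n = 4 and 2), and 1954 had an unadjusted p under 0.05. Over all genes 0 list members passed, and 14 did adjusted over the list alone (9 higher and 5 lower). No list passed by camera (smallest adjusted p = 0.133), and fry, which asks only whether a list's genes move on balance one way, called the cytotoxic granule list (2 tested members, adjusted p = 0.0179). For natural Treg versus natural Foxp3-delta cells no gene was called with the array set as a block or as deposited, and array medians gave 62 higher and 1430 lower with a median shift of -0.13. These groups share no array set, so the block rests on the other groups and cannot tell label from set here. With it the folds of the 6 genes were at 92.3% of their size at the median. The Gapdh 3' to 5' ratio was 1.014 on natural Foxp3-delta array 2 and 1.015 to 1.031 on the natural Treg arrays, while the actin ratio given next differed. The count was 181 without natural Foxp3-delta array 1, 0 without array 2, whose actin 3' to 5' ratio of 2.19 lies above the 1.73 to 1.84 of the natural Treg arrays, and 2 and 1 without natural Treg arrays 2 and 3.

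The arrays labelled activated T and conventional T, which ask what stimulation through the T cell receptor changes, differed in 816 genes. Bend6, a corepressor expressed in neurons, was higher by 1.31 (SE 0.17, adjusted p = 0.000341), Ssc4d by 0.95 (SE 0.18) and Ttyh3 by 0.93 (SE 0.24). The zinc finger gene Zfp931 fell by 1.07 (SE 0.17), the mitochondrial ribosomal gene Mrpl54 by 0.99 (SE 0.15) and Crebl2 by 0.98 (SE 0.25). Of the activation list, 1 of 16 tested members passed: Nr4a1, a nuclear receptor gene induced early after stimulation, was higher by 0.29 (SE 0.07, adjusted p = 0.0187). In the TGF-beta list, Smad7, an inhibitor of TGF-beta signalling, was higher by 0.58 (SE 0.12) and the ligand gene Tgfb1 fell by 0.38 (SE 0.12). With the mean of its probe sets Smad7 had a difference of -0.05 (adjusted p = 0.818), and as deposited Nr4a1 had one of -0.22 (adjusted p = 0.373). Beside these, the oligodendrocyte gene Olig1 fell by 0.44 (SE 0.14) and the neuronal gene Rbfox3 by 0.70 (SE 0.20). Of 7 tested T cell genes Cd3e, a chain of the T cell receptor complex, was higher by 0.81 (SE 0.16, adjusted p = 0.00588), and by 0.21 with the array set as a block (adjusted p = 0.664). These 3 genes were named after their values were seen. By limma 408 genes were called higher and 408 lower (n = 4 and 3), 2967 had an unadjusted p under 0.05, and 22.7% separated the groups against 5.71% by chance. Of the list members 6 were called higher and 5 lower over all genes, and 10 and 13 adjusted over the list alone. No list passed by camera (smallest adjusted p = 0.741), and fry called the activation list (adjusted p = 0.00487). The groups of activated T versus conventional T share no array set. With the set as a block, which rests on the other groups, 12 genes were called, 6 of them among the 816, and none of the 9 genes named by the rule kept its call. Their folds came to 50.3% of their size at the median, from Tgfb1, which changed sign to 0.12 (adjusted p = 0.571), to Smad7, which grew to 0.75 (adjusted p = 0.0596), and Olig1 and Rbfox3 stood at -0.39 and -0.48. As deposited 2 genes were higher and 1365 lower with a median shift of -0.36, and with array medians 3729 were higher and 218 lower with a median shift of 0.17. The count was 1294 without activated T array 1, which is in set 2, 340 and 348 without activated T arrays 2 and 3, and 155, 97 and 191 without conventional T arrays 1, 2 and 3.

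The arrays labelled failed induced Treg, per the labels from cells that met TGF-beta and did not switch on Foxp3, differed from those labelled activated T in 5 genes. Arhgap10, a regulator of the cytoskeleton, was higher by 0.67 (SE 0.12), Atp5g2, a subunit of the mitochondrial ATP synthase, by 0.34 (SE 0.06) and the gene model 2810013P06Rik, named after its values were seen, by 0.49 (SE 0.09). Ssc4d fell by 0.96 (SE 0.18) and Vav2, a signalling protein downstream of cell surface receptors, by 0.46 (SE 0.08). The adjusted p was 0.0336 for each (limma, n = 3 and 4), and no array of one group overlapped the other. Of all genes tested, 7.9% separated these groups, against 5.71% by chance. Of the TGF-beta list no member passed. Smad7 had a difference of -0.55 (SE 0.12, adjusted p = 0.093), and one of 0.02 with the mean of its probe sets. There were 1601 genes with an unadjusted p under 0.05, 0 list members called over all genes and 4 adjusted over the list alone (2 higher and 2 lower), and no list passed (smallest adjusted p = 0.948 by camera). For failed induced Treg versus activated T 1 gene, Vav2, was called with the array set as a block. The folds of the 5 called genes were at 66.9% of their size at the median. As deposited 1 gene was called with a median shift of 0.34, and array medians gave 4 higher and 85 lower with a median shift of -0.12. The count was 0 without failed induced Treg array 1, array 2 or activated T array 3, 49 without failed induced Treg array 3, and 35, 1 and 14 without activated T arrays 1, 2 and 4.

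The arrays labelled induced Treg differed from those labelled activated T, the comparison closest to Foxp3 induction by TGF-beta, in 6 genes. Cdk5r1, a neuronal activator of a cyclin-dependent kinase, was higher by 1.01 (SE 0.17, adjusted p = 0.024), the protease inhibitor gene Ctla2a by 0.81 (SE 0.15), the kinase gene Hipk2 by 0.52 (SE 0.10), the actin regulator Mical2 by 0.36 (SE 0.07) and 2810013P06Rik, again named after its values were seen, by 0.44 (SE 0.08). Col15a1, a basement membrane collagen, fell by 0.54 (SE 0.09). Nt5e, the ecto-nucleotidase of the Treg list, had a difference of 0.30 (SE 0.06, adjusted p = 0.0517). By limma 5 genes were higher and 1 was lower (n = 5 and 4), 1331 had an unadjusted p under 0.05, and 1.91% separated the groups against 1.59% by chance. Over all genes 0 list members passed, and 3 did adjusted over the list alone (1 higher and 2 lower). No list passed by camera (smallest adjusted p = 0.758). For induced Treg versus activated T 4 genes were called with the array set as a block and 0 of the 6 were among them. Their folds stayed at 92.1% of their size at the median. As deposited 7399 genes were higher and 0 lower with a median shift of 0.45. The count was 117 without activated T array 1, 1 without activated T array 2 or 3, and 0 and 1 without induced Treg arrays 1 and 2.

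The arrays labelled induced Treg and failed induced Treg are, per the labels, from the same cultures sorted by the Foxp3 reporter. Between them no gene was called by limma (n = 5 and 3, smallest adjusted p = 0.763), and 509 genes, 4.18% against 5% by chance, had an unadjusted p under 0.05. Foxp3 differed by -0.08 (SE 0.07, interval -0.21 to 0.06). Of the Treg list, Ikzf4, a zinc finger gene, had a difference of 0.08 (SE 0.09, adjusted p = 0.998), and of the TGF-beta list Tgfbi, a secreted matrix protein, one of -0.14 (SE 0.08, adjusted p = 0.998). No list member passed adjusted over the list alone. No list passed by camera (smallest adjusted p = 0.554), and fry called the TGF-beta list (18 members, median -0.05, adjusted p = 0.0331). The count was 0 with the array set as a block and within set 1 (2 arrays against 2), and 1 without set 3 and with array weights.

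Arrays labelled induced Treg and induced Foxp3-delta, which ask what an intact Foxp3 allele adds after induction, gave 0 called genes by limma (n = 5 and 3, smallest adjusted p = 0.678) and 343 with an unadjusted p under 0.05, 2.82% against 5% by chance. Ikzf2, the transcription factor Helios of the Treg list, had a difference of 0.30 (SE 0.12, adjusted p = 1). Foxp3 differed by -0.04 (SE 0.07, interval -0.17 to 0.10). No list member passed over all genes or adjusted over the list alone, and no list passed by camera (smallest adjusted p = 0.647) or fry. The count was 0 with the array set as a block and within set 2 (2 arrays against 2), and 1 without set 3.

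The arrays labelled induced Treg and activated natural Treg, which ask how Treg of different origin differ once stimulated, differed in 787 genes. Capn7, a calpain protease, was higher in the induced label by 0.95 (SE 0.19, adjusted p = 0.00634), the RNA-binding gene Pcbp4 by 0.94 (SE 0.21), the zinc finger genes Zbtb44 and Zfp644 by 0.91 (SE 0.25) and 0.84 (SE 0.20), Lsm12 by 0.83 (SE 0.21) and Tmem181a by 0.83 (SE 0.16). The clathrin adaptor gene Ap2b1 fell by 0.85 (SE 0.25), the protease gene Ctse by 0.84 (SE 0.18), the repressor gene Zhx2 by 0.80 (SE 0.15), Tfam, which packages mitochondrial DNA, by 0.77 (SE 0.13, adjusted p = 0.00413), the ubiquitin ligase gene Hace1 by 0.76 (SE 0.16) and the calcium sensor gene Kcnip3 by 0.74 (SE 0.18). In the interferon list 3 of 14 tested members were higher and 0 lower: Ifit2 by 0.49 (SE 0.11), Ifit1 by 0.41 (SE 0.10) and Oasl2 by 0.32 (SE 0.09). Of these only Ifit2 kept its call with the array set as a block (0.56, limma adjusted p = 0.0428). Ifit1 and Oasl2 then stood at 0.26 (0.212) and 0.28 (0.165). In the Treg list 1 of 16 passed, Entpd1, an ecto-nucleotidase, which fell by 0.35 (SE 0.11, adjusted p = 0.049) and as deposited had a difference of 0.16 (adjusted p = 0.376). The neuronal gene Cplx1 was higher by 0.37 (SE 0.11), and the microglial genes Cx3cr1 and Trem2 by 0.33 (SE 0.09) and 0.38 (SE 0.12). The housekeeping genes Actb and Tbp were higher by 0.33 (SE 0.10) and 0.29 (SE 0.08). These marker genes were named after their values were seen, and with the array set as a block none kept its call. Cx3cr1 then stood at 0.37, Trem2 at 0.20, Cplx1 at 0.15, Tbp at 0.13 and Actb at 0.06. The 3' to 5' signal ratio of the actin control, a measure of RNA integrity, was 2.05, 2.08 and 2.13 on the activated natural Treg arrays and 1.63 to 1.83 on the induced Treg arrays. The same ratio of the Gapdh control did not part the groups, with 0.904 to 1.024 on the activated natural Treg arrays and 0.878 to 1.024 on the induced Treg arrays.

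By limma 388 of these genes were higher and 399 lower (n = 5 and 3), 2912 genes had an unadjusted p under 0.05, and 12.5% separated the groups against 3.57% by chance. Among list members 8 were called higher and 4 lower over all genes, and 15 and 12 adjusted over the list alone. By camera no list passed (smallest adjusted p = 0.926). By fry the interferon and glycolysis lists had an adjusted p of 0.0288 each. For induced Treg versus activated natural Treg 84 genes were called with the array set as a block, 55 of them among the 787, 3 of the 16 genes named by the rule kept their call, and the folds of the 16 were at 56% of their size at the median. As deposited 10854 genes were higher and 0 lower with a median shift of 0.66, and with array medians 231 were higher and 93 lower. The count was 411, 380, 494 and 433 without induced Treg arrays 1 to 4, 1225 without array 5, which is in set 3, and 150 and 438 without activated natural Treg arrays 1 and 2.

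Arrays labelled activated natural Treg and natural Treg differed in 2016 genes. Crb3, an epithelial polarity gene, was higher by 1.43 (SE 0.37, adjusted p = 0.0111), Zhx2 by 1.21 (SE 0.16) and Uroc1, an enzyme of histidine breakdown, by 1.19 (SE 0.38). Cpeb2, a regulator of translation, fell by 1.26 (SE 0.29), R3hdm4 by 1.25 (SE 0.25) and Capn7 by 1.22 (SE 0.19, adjusted p = 0.000681). Of the Treg list 5 of 16 members passed: Entpd1, Itgae and Ikzf2 were higher by 0.46 (SE 0.11), 0.40 (SE 0.11) and 0.39 (SE 0.13), and Gpr83, an orphan receptor gene, and Tnfrsf9 fell by 0.62 (SE 0.13) and 0.27 (SE 0.08). As deposited Entpd1, Itgae and Ikzf2 had differences of -0.04, -0.11 and -0.24. In the glycolysis list 3 of 13 fell and 0 rose: Pgam1 by 0.71 (SE 0.17), Pgk1 by 0.34 (SE 0.10) and Ldha by 0.29 (SE 0.08). With array medians Pgk1 in activated natural Treg versus natural Treg was higher by 0.52 (adjusted p = 0.0289) and Ldha had a difference of 0.03. Of 6 lineage transcription factors Runx1 fell by 0.40 (SE 0.13) and Bcl6 by 0.33 (SE 0.10). The neuronal gene Cplx1 fell by 0.40 (SE 0.12) and the microglial gene C1qb by 0.30 (SE 0.08). The housekeeping genes Actb and Tbp fell by 0.41 (SE 0.10) and 0.32 (SE 0.09), while the housekeeping gene Sdha was higher by 0.31 (SE 0.09). These marker genes were named after their values were seen, and with the array set as a block none kept its call. Cplx1, Actb, Tbp and Sdha then stood at -0.08, -0.04, -0.08 and 0.04. Of 7 tested T cell genes Cd3e and Cd52 were higher by 0.59 (SE 0.16) and 0.24 (SE 0.08) and Rac2 fell by 0.18 (SE 0.06), all named after their values were seen. With the array set as a block Cd3e had a difference of -0.02 (limma adjusted p = 0.973), Cd52 one of 0.005 (0.982) and Rac2 one of -0.08 (0.705). The actin 3' to 5' ratio was 2.05 to 2.13 on the activated arrays and 1.73 to 1.84 on the natural Treg arrays. The Gapdh ratio was not higher on the activated arrays, at 0.904 to 1.024 against 1.015 to 1.031.

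By limma 1047 genes were higher and 969 lower (n = 3 and 4), 3924 had an unadjusted p under 0.05, and 30% separated the groups against 5.71% by chance. Of the list members 17 were called higher and 25 lower over all genes, and 23 and 29 adjusted over the list alone. No list passed by camera (smallest adjusted p = 0.509), and by fry the lineage factor and glycolysis lists had an adjusted p of 0.013 each. In activated natural Treg versus natural Treg all arrays of the first group were in set 3 and all of the second in set 1. With the set as a block, which rests on the other groups, 45 genes were called, 28 of them among the 2016, and none of the 15 genes named by the rule kept its call, with folds at 27.6% of their size at the median. Crb3, Uroc1 and Pgam1 changed sign, to -0.12, -0.50 and 0.09, and Pgk1 and Ldha came to -0.02 and -0.01, so none of the 3 glycolysis falls stood. Ikzf2 (0.42), Bcl6 (-0.36) and C1qb (-0.26) kept folds of about the same size and lost only the call. The marker genes Cplx1, Actb, Tbp, Sdha, Cd3e, Cd52 and Rac2 lost the call with folds that shrank. As deposited 27 genes were higher and 7105 lower with a median shift of -0.52, with array medians 2244 were higher and 514 lower, and the count was 1133 without activated natural Treg array 1.

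**Figure D3:**
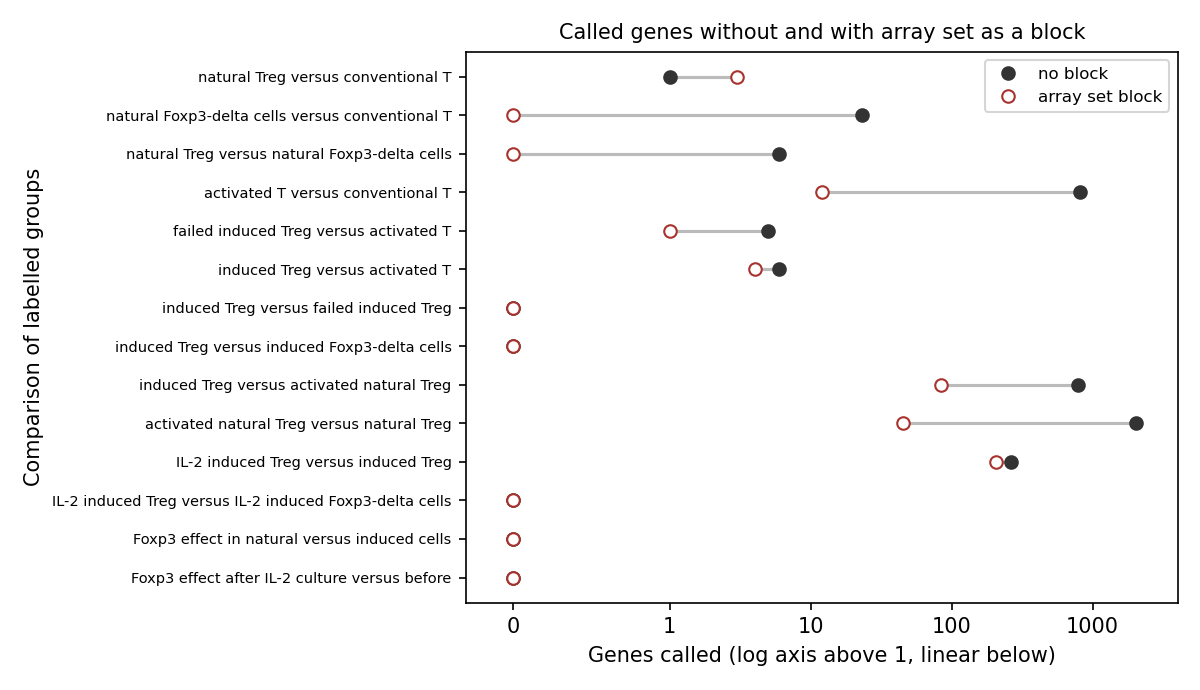
Number of genes called in each of the 14 contrasts (horizontal axis, log scale above 1 and linear below) without a block (filled points) and with the array set as a block (open points). The count goes from 2016 to 45 for activated natural Treg against natural Treg, from 816 to 12 for activated T against conventional T, from 787 to 84 for induced Treg against activated natural Treg and from 265 to 205 for induced Treg with interleukin 2 against induced Treg.

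Arrays labelled induced Treg after a further week in interleukin 2 differed from those labelled freshly induced Treg in 265 genes. Mettl7a1, a methyltransferase-like gene, was higher by 1.07 (SE 0.17, adjusted p = 0.00175), Ccdc136 by 1.05 (SE 0.19) and Pls1 by 0.98 (SE 0.12, adjusted p = 0.000279). Mtmr7, a phosphoinositide phosphatase gene, fell by 1.01 (SE 0.21), the integrin gene Itga3 by 0.96 (SE 0.15) and the tyrosine phosphatase gene Ptpn14 by 0.92 (SE 0.16). In the Treg list 2 of 16 members fell and 0 rose: Cd83, an activation antigen, by 0.53 (SE 0.10) and Tnfrsf9 by 0.37 (SE 0.09). In the interferon list no member passed over all genes, and Oasl2 had a difference of -0.34 (SE 0.10, adjusted p = 0.0839). The microglial gene Cx3cr1 fell by 0.41 (SE 0.11). By limma 124 genes were higher and 141 lower (n = 2 and 5), and 2075 had an unadjusted p under 0.05. Of the list members 0 were called higher and 5 lower over all genes, and 2 and 11 adjusted over the list alone. Camera called no list (smallest adjusted p = 0.255). By fry the Treg, interferon and TGF-beta lists had adjusted p of 0.00713, 0.0264 and 0.0427. For IL-2-cultured induced Treg versus induced Treg 205 genes were called with the array set as a block, 114 of them among the 265, and the 8 genes named by the rule kept their call, with folds at 98.3% of their size at the median, while Cx3cr1 lost its call at an unchanged fold (-0.43, adjusted p = 0.072). Within set 1 (2 arrays against 2) 252 were called, 84 of them among the 265, and without set 3 there were 686. As deposited 0 genes were called with a median shift of -0.30, and with array medians 39 were higher and 527 lower with a median shift of -0.14. The count was 16 and 29 without either of the arrays with interleukin 2, and 140 and 149 without induced Treg arrays 3 and 4.

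Between arrays labelled induced Treg and induced Foxp3-delta after interleukin 2, no gene was called by limma (n = 2 and 2, smallest adjusted p = 0.379), and 349 genes, 2.87% against 5% by chance, had an unadjusted p under 0.05. Cd83 had the smallest p of the Treg list, with a difference of -0.60 (SE 0.12, adjusted p = 0.379). Foxp3 differed by -0.01 (SE 0.09, interval -0.19 to 0.18). Of the list members 0 passed over all genes and 3, all lower, adjusted over the list alone. The Treg list had the smallest adjusted p by camera, 0.0618, and one of 0.0916 with an estimated correlation. All 4 arrays were in set 1, where the count was also 0, and array weights gave 4.

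A difference between 2 such contrasts was tested directly by interaction. Whether the intact and mutant Foxp3 labels differed otherwise in natural than in induced cells was not seen in any gene by limma (0 called, smallest adjusted p = 0.157, 554 with an unadjusted p under 0.05). Foxp3 had an interaction of 0.17 (SE 0.10). Whether they differed otherwise after interleukin 2 than before gave 0 genes as well (smallest adjusted p = 1, 349 with an unadjusted p under 0.05), and Foxp3 had an interaction of 0.03 (SE 0.11). Both counts stayed 0 with the array set as a block, and the first was 9 without natural Foxp3-delta array 1. Of the list members, 0 in the first and 2 in the second passed adjusted over the list alone, and no list passed by camera (smallest adjusted p = 0.225 and 0.15).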

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

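In groups of 4 or 5 arrays, the highest or lowest array was compared with its nearest neighbour by Dixon's test for each named gene and marker list. All these tests followed a rule fixed beforehand, applied to genes named from the results. Of 110 tests 9 marked an array as standing apart, where 5.5 are expected by chance.

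5 of the 9 concern array 5 labelled induced Treg. Col15a1 was higher there, with a log2 intensity of 6.07 against 5.77 to 5.85 on the other 4, and so was Nt5e, with 6.78 against 6.51 to 6.54. Zbtb44 was lower, at 7 against 7.95 to 8.15, as was Mtmr7, at 8.5 against 8.9 to 9.06, and the neuron list had a median percentile of 99.4 against 99.5. This array is the only one of its group in array set 3. Without it 1225 genes in place of 787 were called for induced Treg versus activated natural Treg.

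The other 4 are single genes. Mbp, the major myelin protein, had a deposited intensity of 12300 on array 3 labelled activated T against 21600 to 22800 on the other 3, and that array also had the lowest median of all (22.21). Crebl2 was at 8.26 on array 4 labelled activated T against 8.55 to 8.59. Snrpb2 was at 9.23 on array 1 labelled natural Treg against 9.44 to 9.47, and Itgae at 5.54 on array 2 labelled natural Treg against 5.63 to 5.64. Snrpb2 and Crebl2 had lower values on these arrays by less than the differences reported for them between groups, 0.75 for Snrpb2 against natural Foxp3-delta and -0.98 for Crebl2 against conventional T.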

How the results depend on the processing

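Tests chosen after values had been seen are those with the array set as a block, the control ratio as a covariate, single array sets and the arrays without set 3. The report's counts rest on quantile normalisation, and values as deposited had been the setting fixed beforehand. Of 325 alternative counts 202 stayed within 1.5 times the reported count and the others did not. Of 1717 alternative values for 82 results on named genes, 1151 kept direction and call, 528 kept the direction and lost the call, 21 gained a call and 17 changed sign. With the array set as a block these numbers were 21, 56, 1 and 4 of 82. The cause of a change under a setting was not tested unless a test is given below.

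How arrays were scaled moved most counts. For values as deposited the count was 0 for natural Treg versus conventional T, 0 for natural Foxp3-delta cells versus conventional T, 0 for natural Treg versus natural Foxp3-delta cells, 1367 for activated T versus conventional T, 1 for failed induced Treg versus activated T, 7399 for induced Treg versus activated T, 10854 for induced Treg versus activated natural Treg, 7132 for activated natural Treg versus natural Treg and 0 for IL-2-cultured induced Treg versus induced Treg. The sign changed for Nr4a1 in activated T versus conventional T (-0.216), Entpd1 in induced Treg versus activated natural Treg (0.158), and Entpd1 in activated natural Treg versus natural Treg (-0.0375), with Ikzf2 in activated natural Treg versus natural Treg (-0.242) and Itgae in activated natural Treg versus natural Treg (-0.109). With array medians the count was 586 for natural Foxp3-delta cells versus conventional T, 1492 for natural Treg versus natural Foxp3-delta cells, 3947 for activated T versus conventional T, 89 for failed induced Treg versus activated T, 324 for induced Treg versus activated natural Treg and 566 for IL-2-cultured induced Treg versus induced Treg. There Ldha in activated natural Treg versus natural Treg (0.0273) and Pgk1 in activated natural Treg versus natural Treg (0.516) changed sign. The median over all genes moved under these scalings, most of all as deposited for induced Treg versus activated natural Treg (0.66), so an excess of genes in 1 direction there follows the scaling. Median shifts not given in the report were 0.12 for induced Treg versus failed induced Treg, -0.12 for the induced pair after interleukin 2, -0.11 for the second interaction as deposited and -0.14 for the first with array medians.

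Choices on genes moved fewer. A pseudocount of 64 gave 2 genes for natural Treg versus conventional T and 3 for failed induced Treg versus activated T, and a pseudocount of 1 gave 9 for the latter. The strict filter gave 2 for failed induced Treg versus activated T and 3 for induced Treg versus activated T, and no filter gave 11 for induced Treg versus activated T. With the mean of probe sets the count was 0 for natural Treg versus conventional T, 0 for natural Foxp3-delta cells versus conventional T and 143 for IL-2-cultured induced Treg versus induced Treg. Smad7 in activated T versus conventional T (-0.0495), Smad7 in failed induced Treg versus activated T (0.0225), Tgfbi in induced Treg versus failed induced Treg (0.0118) and Pgk1 in activated natural Treg versus natural Treg (0.116) changed sign. The number of gene lists called over all contrasts, 0 with camera, was 10 with fry, 9 for values as deposited, 13 with array medians, 1 with no filter and 2 with the strict filter.

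The model mattered as well. Fitting the groups of the contrast alone gave 3 genes for natural Treg versus conventional T, 3 for natural Foxp3-delta cells versus conventional T, 141 for natural Treg versus natural Foxp3-delta cells, 384 for activated T versus conventional T, 0 for failed induced Treg versus activated T, 0 for induced Treg versus activated T, 64 for induced Treg versus activated natural Treg and 4 for IL-2-cultured induced Treg versus induced Treg. Array weights gave 16 for natural Treg versus conventional T, 0 for natural Foxp3-delta cells versus conventional T, 1547 for activated T versus conventional T, 492 for failed induced Treg versus activated T, 1 for induced Treg versus failed induced Treg, 479 for induced Treg versus activated natural Treg, 1255 for IL-2-cultured induced Treg versus induced Treg and 4 for IL-2-cultured induced Treg versus IL-2-cultured induced Foxp3-delta cells.

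The replicate block gave 271 for natural Foxp3-delta cells versus conventional T, 481 for natural Treg versus natural Foxp3-delta cells, 1 for induced Treg versus activated T, 1407 for induced Treg versus activated natural Treg and 77 for IL-2-cultured induced Treg versus induced Treg, with Ikzf4 in induced Treg versus failed induced Treg at -0.00969. Arrays of like number correlated, after group means were removed, between -0.228 and 0.316 over all comparisons, and in none did every pair exceed 0.1, so the numbers were not read as pairs. The highest were 0.307 and 0.316, for arrays 1 and 2 of induced and failed induced Treg, while array 3 gave 0.0449. Arrays 1 and 2 of both groups are in set 1 and arrays 3 in sets 2 and 3, so pairing and set cannot be told apart there. A pairing by culture stays open for these groups, and the main comparison leaves it out.

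The technical array sets moved the largest counts. With the array set as a block the count was 3 for natural Treg versus conventional T, 0 for natural Foxp3-delta cells versus conventional T, 0 for natural Treg versus natural Foxp3-delta cells, 12 for activated T versus conventional T, 1 for failed induced Treg versus activated T, 84 for induced Treg versus activated natural Treg and 45 for activated natural Treg versus natural Treg. Tgfb1 in activated T versus conventional T (0.124), Crb3 in activated natural Treg versus natural Treg (-0.119), Pgam1 in activated natural Treg versus natural Treg (0.0888) and Uroc1 in activated natural Treg versus natural Treg (-0.502) changed sign. With the control ratio as a covariate it was 2 for natural Treg versus conventional T, 0 for natural Foxp3-delta cells versus conventional T, 1 for natural Treg versus natural Foxp3-delta cells, 79 for activated T versus conventional T, 16 for failed induced Treg versus activated T, 0 for induced Treg versus activated T, 24 for induced Treg versus activated natural Treg and 7 for activated natural Treg versus natural Treg, where Uroc1 was at -0.194. Without array set 3 it was 2 for natural Treg versus conventional T, 1 for natural Foxp3-delta cells versus conventional T, 0 for natural Treg versus natural Foxp3-delta cells, 4 for activated T versus conventional T, 1 for induced Treg versus failed induced Treg, 1 for induced Treg versus induced Foxp3-delta cells and 686 for IL-2-cultured induced Treg versus induced Treg. Array set 1 only gave 3 for natural Treg versus conventional T, array set 2 only gave 0 for induced Treg versus activated T, and array set 3 only gave 0 for failed induced Treg versus activated T, induced Treg versus activated T and induced Treg versus activated natural Treg. Except in set 1 these have 1 array on one side (1 against 3 in set 3, 2 against 1 in set 2) and take the spread from the other arrays of the set, so these counts of 0 say little.

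Leaving out single arrays gave 0 to 3 genes for natural Treg versus conventional T, 0 to 135 for natural Foxp3-delta cells versus conventional T, 0 to 181 for natural Treg versus natural Foxp3-delta cells, 97 to 1294 for activated T versus conventional T, 0 to 49 for failed induced Treg versus activated T, 0 to 117 for induced Treg versus activated T, 150 to 1225 for induced Treg versus activated natural Treg, 1133 to 1800 for activated natural Treg versus natural Treg, 16 to 303 for IL-2-cultured induced Treg versus induced Treg and 0 to 9 for the interaction of natural with induced cells. It gave 0 throughout for induced Treg versus failed induced Treg, induced Treg versus induced Foxp3-delta cells, the induced pair after interleukin 2 and the other interaction. Where a group was left with 1 array, that array was assumed to vary like the other groups. Of called named genes, those called without every array in turn were 4 of 9 for activated T versus conventional T, 5 of 16 for induced Treg versus activated natural Treg, 7 of 15 for activated natural Treg versus natural Treg, 1 of 8 for IL-2-cultured induced Treg versus induced Treg and 0 in the other comparisons.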

Other observations

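Tests chosen only after the result was seen are those of housekeeping, T cell, myelin and neuron percentiles, all tests with the array set as a block and the look at how splits part array set 3, while the probe set correlation and the splits of the arrays were fixed before their results were seen.

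The first pattern is that genes of myelin, neurons and astrocytes are among the brightest on all 31 arrays and T cell genes, Foxp3 included, are not. Failed arrays are argued against by housekeeping genes, whose median percentile was at least 99.1 on every array. Dim arrays cannot be judged this way, since a percentile is a rank within an array. Activated T array 3, with the lowest deposited median (22.21), had a housekeeping percentile of 99.27. Identifiers out of step with the values are argued against by the 9012 genes with several probe sets, whose levels had a rank correlation of 0.4474 where the highest of 1000 shuffled pairings gave 0.0415. A mainly T cell RNA with some nervous tissue is argued against by the T cell list, whose median percentile reached at most 46.64, though a small share of T cell RNA stays open. Intensities of other RNA under these labels stay open: the myelin and neuron lists lay at 99.01 or higher on every array, but these lists were drawn up after the brightest probe sets had been seen, so this restates the pattern and adds no support, and no biological explanation was tested.

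Sex-linked genes were looked at apart from this. Xist at 1719 or more with Y-linked genes at 12.3 or less is the pattern of female RNA, also on arrays labelled as from mutant males. Where values and labels came apart, in the deposit or before it, cannot be seen from these tables.

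The second pattern is that, without a block, the largest counts of genes lie between label groups in different technical array sets. Activated natural Treg versus natural Treg went from 2016 genes to 45 with the array set as a block, and activated T versus conventional T from 816 to 12. These pairs share no array set, so label and set cannot be told apart in them. A difference between the RNA samples so labelled, whatever cells they came from, stays open as well. Induced Treg versus activated natural Treg went from 787 to 84, and to 24 with the control ratio as a covariate. With the block the folds of 16 named genes were at 56% of their size at the median. The 7 other splits that part set 3 as far as the labels do called at most 57 genes, so membership of set 3 alone does not give the count. Set 3 is not uniform, though. The control ratio was 6.19 to 6.25 on the activated natural Treg arrays and 5.96 on induced Treg array 5. Technical differences therefore stay open for the count as a whole. IL-2-cultured induced Treg versus induced Treg had 205 genes with the block, of which 114 were among the 265, and 252 within set 1 alone, which argues against array sets as its whole cause and leaves them open for the genes of the 265 that were lost.

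The third pattern is how the counts compare with other splits of the same arrays. In induced Treg versus activated natural Treg (787 genes) the real split alone reached its count, 1 of 56, highest other 63. So it did in activated natural Treg versus natural Treg (2016, 1 of 35, highest other 17). This argues against chance without excluding it, since 1 split is the fewest possible and several comparisons were tested without adjustment. In activated natural Treg versus natural Treg no other split parts set 3 as far, so label and array set stay together there. For natural Treg versus conventional T (1 gene) 4 of 35 splits were as large, highest other 1. For activated T versus conventional T (816 genes) it was 2 of 35. The other split there, with 892, set the 3 activated T arrays of set 3 against all the rest. For induced Treg versus activated T (6 genes) it was 5 of 100 splits drawn, highest other 116. For failed induced Treg versus activated T (5 genes) it was 8 of 35, highest other 831. Chance is not argued against in any of these. With 0 real genes the splits can say nothing on chance for induced Treg versus induced Foxp3-delta cells (56 of 56, highest other 7) and induced Treg versus failed induced Treg (56 of 56, highest other 761). The highest splits with 116, 831 and 761 genes each put all set 3 arrays on one side, which points to a structure of the arrays other than their labels.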
